A study of Mus musculus with 120 samples.

How the data were processed

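The livers of 60 male mice of 30 strains, 2 males per strain, were measured on 120 short-oligonucleotide arrays, 2 per male. Arrays were assigned to strain and male from the sample labels, taking the animal number in the label as the male, which the labels do not state. The deposited values are log2 signals per probe set, already normalized between arrays by the authors, since the quantiles of all arrays nearly coincide. The summary method, the log base and the normalization are not given in the sources used here, and the base was read from the range of the values (6.34 to 14.82). Read from the values, the deviations of a probe set between arrays are shrunk by a factor that differs from probe set to probe set, so a difference between strains is not a log2 fold change and cannot be compared in size between genes. No absolute detection call was used. A pseudocount does not apply to values that are already logarithms.

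The table held 45037 probe sets, of which 35877 were in the annotation table and 34945 carried a single gene symbol. Of these, 34741 matched a gene of the reference table by gene ID and 204 did not. The 932 probe sets with several symbols and the 9160 with none were set aside. For each of the 18193 genes the probe set with the highest mean was kept. Genes were tested if at least 2 of the 60 males exceeded the median of all values, 7.417, which left 11949 genes, 45 of them without a chromosome. Gene symbols, chromosomes and gene order come from the reference annotation of GRCm38.p6. The build behind the deposited table is not named, so no coordinates are given.

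The 2 arrays of a male were averaged, and limma was fitted with 1 mean per strain over all 30 strains, with 30 residual degrees of freedom and a prior of 0.592 degrees of freedom from empirical Bayes moderation. Each of 29 contrasts set a strain against B6. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg within each contrast). Calls in a consomic strain were split into those on the substituted chromosome (the whole chromosome for the C and T strains, whose boundaries the labels do not give) and those elsewhere, and compared by a two-sided Fisher's exact test, adjusted over the strains. Shares of calls carry exact 95% binomial intervals (Clopper-Pearson), which treat the calls as independent. As a second reference, each strain was set against the mean of all strains that carry no part of the same chromosome from MSM, MSM itself excluded and B6 included. The Chr7 strain was compared with the sum of its part strains as a contrast in the same fit. The share of the MSM difference carried by a strain is the median, over genes of a chromosome called in MSM against both references, of the strain's distance from the other strains divided by that of MSM, where the other strains exclude B6, MSM and any strain with part of that chromosome.

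Of 32 gene lists written beforehand, 30 had at least 2 tested genes and were tested in every contrast with camera at a preset correlation of 0.01, with camera at a correlation estimated from the residuals, and with fry, adjusted over all 870 tests. The lists covered cholesterol synthesis, fatty acid and triglyceride synthesis, PPARA targets, bile acids, gluconeogenesis and glycolysis, xenobiotic metabolism, male- and female-biased liver genes, the acute phase, complement and coagulation, interferon response, MHC genes, the circadian clock, heat shock, endoplasmic reticulum stress, NRF2 targets, glucocorticoid and fasting response, the respiratory chain, the mitochondrial genome, chromosome Y, ribosome, cell cycle, and markers of Kupffer cells, lymphocytes, neutrophils, erythroid cells, stellate cells, endothelium, cholangiocytes, pancreas, adipocytes and muscle. Members were also counted with p adjusted over the list alone.

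Genes were named by a fixed rule. For MSM it took the 12 largest higher and the 12 largest lower called genes in which both MSM males lay beyond both B6 males. For each consomic strain it took the 3 largest on the substituted chromosome and the 3 largest elsewhere under the same condition. Across strains it took the 20 genes called elsewhere in most strains, and in each contrast up to 4 called members of each list with the largest absolute change, with the chromosome Y and mitochondrial lists in the strains that carry those from MSM. The contrasts, lists, naming rule and the alternatives to each choice were fixed before the data were examined. The rule for males that stand apart (beyond the other 59 males by more than their whole range) and the scaling used to remove array factors were settled after the data were seen.

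The overlap of strain calls with MSM calls was compared with independent lists of the same sizes, the correlation of the differences with 100 simulated data sets in which the strains share only the B6 males, and the recurrence of genes between strains with 1000 random draws. The pipeline was tested on simulated data with known changes. Of 50 genes changed by 4 residual SDs it called 28, and all 50 at each of 6, 8 and 10 SDs, with 6 of the unchanged genes called. It called 40 of 40 changed genes of a chromosome, 10 of 10 genes with an added term against 0 of 50 additive genes in the chromosome 7 comparison, and 0 of 50 lists of 20 unchanged genes at an unadjusted camera p below 0.05. The simulated genes varied independently, so the last count does not test camera on lists of correlated genes.

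Alternatives were quantile normalization, no filter, a filter at the 70th percentile of all values, the mean over probe sets of a gene, all arrays with the male as a random block (consensus correlation 0.325), empirical Bayes moderation with trend and robust, a minimum change of 1 on the log2 scale, a fit on MSM and B6 alone, the panel reference, and leaving out each male in turn. With 1 male left, a strain is assumed to vary like the others. Other fits were added after the data were seen: one with the 5 factors that each took more than 5% of the differences between arrays of the same male removed, one with quantile normalization and an estimated correlation in camera, one without the first Chr9 male and one without the first Chr7T male. The software was R 4.3.3 with limma 3.58.1, version 1.17.8 of data.table and statmod 1.5.0.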

Results

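Transcript levels were measured in the livers of 10-week-old male mice after 4 h of fasting, on 120 whole-genome expression arrays. The panel held 30 strains. C57BL/6J (B6) was the control, MSM/Ms (MSM) is an inbred strain derived from Japanese wild mice, and the other 28 strains were consomic: each carries 1 MSM chromosome, or its centromeric (C) or telomeric (T) part, on the B6 background. Such a panel asks which liver transcript differences between MSM and B6 travel with which chromosome. Every strain was represented by 2 males and every male by 2 arrays, so each comparison below sets 2 males against 2 males (n = 2), and this number of arrays limits the precision. The deposited log2 signals ran from 6.34 to 14.82, and the medians of the arrays all lay between 7.416 and 7.417. Most genes moved very little on this scale: the median over genes of the residual SD between males of a strain was 5.95e-05, with a 10th percentile of 1.02e-05 and a 90th percentile of 0.00081. Differences are therefore given on the deposited log2 scale with their standard error (SE), and are not fold changes. Across genes scaled to a common spread, arrays of the same male had a median correlation of 0.37 (60 pairs), arrays of the other male of the strain 0.081 (120 pairs) and arrays of other strains −0.023 (6960 pairs). The array that correlated best was the other one of the same male for 43 of the 120 arrays and one of the same strain for 49. The labels do not state that arrays with the same animal number come from 1 male, and every n = 2 rests on reading them so.

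The comparison of MSM with B6 asked how the livers of the parental strains differ. Wfdc21, which encodes a secreted protein of the whey acidic protein family, stood at −2.83 ± 0.11 (SE) on the deposited log2 scale (adjusted p = 3.42e-19). Cyp4a14, a microsomal fatty acid hydroxylase and classical PPARA target, fell by 1.73 ± 0.22 (adjusted p = 6.6e-07). Several drug- and steroid-metabolising enzymes fell too, among them Cyp2d26 (−1.22 ± 0.033), Ugt3a2 (−1.0 ± 0.039), Cyp2c37 (−0.75 ± 0.16), the retinol dehydrogenase Rdh16f2 (−0.67 ± 0.067), Hsd3b3 (−0.62 ± 0.039) and the carboxylesterase Ces2a (−0.54 ± 0.018). The plasma protease inhibitor Mug1 (−0.84 ± 0.029), the pantetheinase Vnn1 (−0.43 ± 0.049) and the innate immune receptor Nlrp12 (−0.43 ± 0.061) also fell. The male-predominant steroid reductase Hsd3b5 was lower by −1.62 ± 0.49 (adjusted p = 0.0153), and its adjusted p was 0.0804 without B6 male 1, 0.0691 without B6 male 2, 0.0522 without MSM male 1 and 0.101 without MSM male 2.

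Among genes higher in MSM, Cyp2c39, a cytochrome P450, rose by 0.75 ± 0.028 (adjusted p = 1.12e-19). The steroid dehydrogenase Akr1c18 rose by 0.42 ± 0.0071 (adjusted p = 7.79e-29), the caveolar coat protein Cav1 by 0.35 ± 0.031, the rhythmically expressed gene Noct by 0.27 ± 0.056 and the fibrillar collagen Col5a2 by 0.22 ± 0.033. Also higher were Slc25a25 (0.22 ± 0.038), Plk3 (0.19 ± 0.042), Sult5a1 (0.13 ± 0.016), Mmd2 (0.13 ± 0.020) and Cyp2d13 (0.11 ± 0.015). The metallothioneins Mt2 (1.08 ± 0.34, adjusted p = 0.0172) and Mt1 (0.63 ± 0.21, adjusted p = 0.0264), which bind zinc and copper, were also higher. The Mt2 call was lost without B6 male 1 (adjusted p = 0.229) and without MSM male 2 (adjusted p = 0.127). That of Mt1 was lost without B6 male 1 (adjusted p = 0.265), MSM male 1 (adjusted p = 0.0608) and MSM male 2 (adjusted p = 0.161).

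In all, limma called 1731 of 11949 genes higher and 1226 lower in MSM, and in 1730 of the genes called higher and 1226 of those called lower both MSM males lay beyond both B6 males. The naming rule took 95 MSM differences, some of which are only counted below, and 61 of the 95 passed the threshold in each of the 4 fits with 1 of the 4 males left out. The counts fell to 919 higher and 705 lower without B6 male 1, 1046 and 878 without B6 male 2, 1004 and 848 without MSM male 1, and 987 and 724 without MSM male 2. A minimum change of 1 on the log2 scale left 1 gene higher, Mt2, and 5 lower, Wfdc21, Cyp4a14, Hsd3b5, Cyp2d26 and Ugt3a2. A fit on these strains alone called 581 higher and 739 lower. Quantile normalization of the deposited values called 9785 higher and 344 lower, and shifted the median gene in MSM from 0.592 to 6.02 residual SDs above B6.

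Genes of lipid and sterol metabolism moved in several directions in MSM. Of 20 genes of cholesterol synthesis, 6 rose and none fell (0 of 20), both over all genes and adjusted over the list alone. Among them were the isomerase Idi1 (0.066 ± 0.014, adjusted p = 0.00087), the reductase Dhcr7 (0.015 ± 0.0030) and the squalene synthase Fdft1 (0.014 ± 0.0032). Of 19 genes of fatty acid and triglyceride synthesis, 1 rose and 6 fell. The stearoyl-CoA desaturase Scd1 dropped by 0.26 ± 0.019 (adjusted p = 5.19e-12), while the calls of Srebf1 (−0.023 ± 0.0080), which encodes a lipogenic transcription factor, and the citrate lyase Acly (−0.0059 ± 0.0019) were lost with any of the 4 males left out (adjusted p from 0.0634 to 0.190). Of 24 PPARA targets and fatty acid oxidation genes, 2 rose, among them the thioesterase Acot4 (0.027 ± 0.0038), and 4 fell, among them Cyp4a14, Vnn1 and Acaa1b (−0.0017 ± 0.00022), but under quantile normalization 4 were called higher and 2 lower. Of 18 bile acid genes, none rose (0) and 3 fell: the conjugating enzyme Baat (−0.0034 ± 0.00035), the bile salt export pump Abcb11 (−0.0029 ± 0.00061) and the ligase Slc27a5 (−0.0022 ± 0.00035). Quantile normalization called 2 bile acid genes higher and 3 lower. Of 15 genes of gluconeogenesis and glycolysis, Pfkl rose (0.014 ± 0.0012) and Pgm1 fell (−0.00069 ± 0.00014), and quantile normalization turned the direction of Pgm1 (0.000098). Without B6 male 1, B6 male 2, MSM male 1 and MSM male 2 in turn, 5, 4, 4 and 5 genes of cholesterol synthesis rose, 1, 3, 1 and 2 of fatty acid and triglyceride synthesis fell, and of the PPARA targets 3, 1, 4 and 2 rose and 3, 4, 3 and 3 fell. Of the gluconeogenesis and glycolysis genes 2 rose without MSM male 1, and the bile acid counts did not change. None of these lists differed from the other genes in camera as deposited (adjusted p from 0.0927 to 0.730). Under quantile normalization the lists of fatty acid synthesis (adjusted p = 3.91e-05), PPARA targets (adjusted p = 7.07e-05) and bile acids (adjusted p = 8.7e-05) were lower than other genes with the preset correlation, and with an estimated correlation too (adjusted p = 0.00324, 0.00529 and 0.00428), which no list passed as deposited. It also moved the median gene as given above, and 12 genes of cholesterol synthesis, 3 of fatty acid synthesis and 7 of gluconeogenesis and glycolysis were called higher.

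Of 38 genes of xenobiotic metabolism, 7 rose and 11 fell in MSM (8 and 11 adjusted over the list alone), and quantile normalization called 10 higher and 9 lower. The glutathione transferase Gstm3 stood at −0.41 ± 0.11 (adjusted p = 0.0066), and 0.0546 without B6 male 2. Of 16 NRF2 targets, 3 rose and 6 fell, among them the carbonyl reductase Cbr1 (−0.055 ± 0.0088) and the thioredoxin reductase Txnrd1 (−0.040 ± 0.0051). Of 13 male-biased liver genes, 3 fell, including the urinary protein gene Mup3 (−0.41 ± 0.041, adjusted p = 4.95e-09), and 1 rose, Susd4 (0.018 ± 0.0041). Of 10 female-biased genes, 1 rose, Fmo2 (0.0014 ± 0.00033, adjusted p = 0.0531 without MSM male 2). Of 18 glucocorticoid and fasting response genes, 4 rose, among them Mt2, Mt1 and the stress-induced Ddit4 (0.11 ± 0.018), and none fell (0). Of 28 acute phase genes, 3 rose and 5 fell (4 and 5 adjusted over the list alone), among them the iron hormone Hamp at −0.25 ± 0.076, whose call was lost with any of the 4 males left out (adjusted p from 0.0551 to 0.0846). Quantile normalization called 6 acute phase genes higher and 4 lower, 4 and 5 NRF2 targets, 2 and 3 male-biased, 4 and 1 female-biased, and 10 and 0 glucocorticoid and fasting response genes. With the same males left out in that order, 5, 5, 4 and 5 xenobiotic metabolism genes rose and 9, 8, 8 and 9 fell, and of the NRF2 targets 1, 1, 1 and 2 rose and 5, 5, 5 and 6 fell. In the male-biased list 1, 2, 1 and 1 fell, in the glucocorticoid and fasting list 2, 3, 3 and 1 rose, and in the acute phase list 1, 3, 2 and 1 rose and 3, 4, 4 and 3 fell. The median and the mean of the list had opposite signs for the male-biased, acute phase and NRF2 lists.

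Of 25 interferon response genes, 10 fell and none rose (0), and 23 had a negative difference. Rtp4 fell by 0.027 ± 0.0056 (adjusted p = 0.000716) and Trim30a by 0.0051 ± 0.00095. The list was lower than other genes in camera with a preset correlation (adjusted p = 0.00093), but adjusted p = 0.645 with an estimated correlation, and quantile normalization called 7 members higher and 4 lower. The 10 lower calls came to 7 without either B6 male or MSM male 1 and 6 without MSM male 2, and that of Rsad2 was lost with any of these males left out (adjusted p from 0.0996 to 0.129). Of 16 Kupffer cell and macrophage markers, 4 fell and 1 rose, with Csf1r, the receptor that maintains macrophages, at −0.024 ± 0.0056 (adjusted p = 0.00217). Of the other lower calls, that of Vsig4 was lost with any of the 4 males left out (adjusted p from 0.106 to 0.138). Clec4f passed only without B6 male 2 (adjusted p = 0.0455), and Lyz2 was lost without B6 male 2 (0.0569) or MSM male 2 (0.0525), so that 2 markers were lower without either B6 male or MSM male 1 and 1 without MSM male 2, with none higher (0). As deposited this list was lower in camera (adjusted p = 0.0419, and adjusted p = 0.837 with an estimated correlation). The second MSM male was the lowest of all 60 males in 15 of 34 measured interferon genes and 11 of 18 measured Kupffer cell markers. Of 29 complement and coagulation genes, 6 fell and 2 rose, with C8a at −0.084 ± 0.0083, Klkb1 at −0.019 ± 0.0018 and prothrombin, F2, at −0.00093 ± 0.000098 (camera adjusted p = 0.0188, and adjusted p = 0.60 with an estimated correlation), while 12 of the 29 had a positive difference. Quantile normalization called 2 Kupffer cell markers higher and 3 lower, and 2 and 4 complement and coagulation genes. Of 17 MHC and antigen presentation genes, 4 fell and 1 rose, Tap2 (0.00014 ± 0.000030), while quantile normalization called 4 higher and 3 lower. The lower calls of H2-D1 (adjusted p from 0.101 to 0.157) and H2-K1 (0.0983 to 0.178) were lost with any of the 4 males left out, and Nlrc5 passed only without MSM male 1 (0.0397). No MHC gene was lower without either B6 male or MSM male 2 (0), and 1 was without MSM male 1, while Tap2 held in each of these fits. Of the complement and coagulation genes 5 were lower without B6 male 1 or either MSM male and 6 without B6 male 2, with 1 higher each time. With an estimated correlation camera called none (0) of the 30 lists in MSM, and 2 had an unadjusted p below 0.05.

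The members of the remaining lists called in MSM as deposited are given next. Of all 11949 tested genes, 2957 were called in MSM. Of 20 circadian genes, Noct and Cry2 (0.0010 ± 0.00022) rose. Of 14 heat shock genes 2 rose and 1 fell, the small chaperone Hspb1 (−0.075 ± 0.019). Of 22 endoplasmic reticulum stress genes 1 rose and 1 fell (1 and 0 adjusted over the list alone). Of 41 nuclear genes of the respiratory chain 5 rose and 2 fell (5 and 1 adjusted over the list alone), and the mitochondrially encoded ND5, the single tested gene of its list, rose by 0.00072 ± 0.00012 (adjusted p = 5.1e-05). Of 20 cytosolic ribosome genes 2 rose and 3 fell, of which Rps6 (−0.0021 ± 0.00034) turned positive under quantile normalization (0.00047). In the list of 12 cell cycle genes 1 rose and 1 fell. Among 6 erythroid markers, the heme synthesis enzyme Alas2 fell by 0.10 ± 0.016 and the transferrin receptor Tfrc rose by 0.080 ± 0.018, with 1 higher and 2 lower over all genes and 2 and 3 adjusted over the list alone. In the list of 14 stellate and fibroblast markers 1 rose and 1 fell (0 and 1 adjusted over the list alone), and the same counts over all genes held for 11 endothelial markers, among them Lyve1 (0.040 ± 0.010) and Clec4g (−0.0019 ± 0.00056), whose call was lost without B6 male 1 (adjusted p = 0.0769) or MSM male 2 (0.0778) and which turned to 0.00040 under quantile normalization. Of 3 cholangiocyte markers Krt23 (0.037 ± 0.0087) and Epcam (0.000057 ± 0.000014, adjusted p = 0.0659 without B6 male 2) rose, and of 4 adipocyte markers Car3 (−0.015 ± 0.0018) and Pparg (−0.0021 ± 0.00052, adjusted p = 0.0632 without B6 male 1) fell. Of 4 neutrophil markers Cxcr2 rose (0.00011 ± 0.000026). No member of the 9 lymphocyte, 6 pancreas or 3 muscle markers, and not Sry, the single tested Y chromosome gene of its list, was called (0). With B6 male 1, B6 male 2, MSM male 1 and MSM male 2 left out in turn, 0, 1, 1 and 1 endoplasmic reticulum stress genes rose and none fell (0), 3 respiratory chain genes rose each time and 0, 1, 1 and 0 fell, and 0, 1, 0 and 0 ribosome genes rose and 2 fell each time. Of the cell cycle genes 0, 1, 1 and 0 rose and 0, 1, 0 and 0 fell, of the erythroid markers 1, 2, 2 and 1 fell, and the higher stellate marker was lost each time. Under quantile normalization more members were called higher: 11 of 20 circadian, 6 of 14 heat shock, 4 of 22 endoplasmic reticulum stress, 6 of 41 respiratory chain, 3 of 20 ribosome and 8 of 12 cell cycle genes. Among the markers it called higher 9 of 9 lymphocyte, 4 of 4 neutrophil, 4 of 6 erythroid, 8 of 14 stellate, 9 of 11 endothelial, 3 of 3 cholangiocyte, 5 of 6 pancreas, 1 of 4 adipocyte and 3 of 3 muscle markers. Over all lists in MSM, camera with the preset correlation passed 3 of 30 as deposited and 16 under quantile normalization, each lower than other genes. With an estimated correlation 0 passed as deposited and 10 under quantile normalization. In fry, which tests whether the genes of a list move on balance, 2 lists passed in MSM, the cholangiocyte (adjusted p = 0.0271) and adipocyte markers (adjusted p = 3.77e-05).

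**Figure D1:**
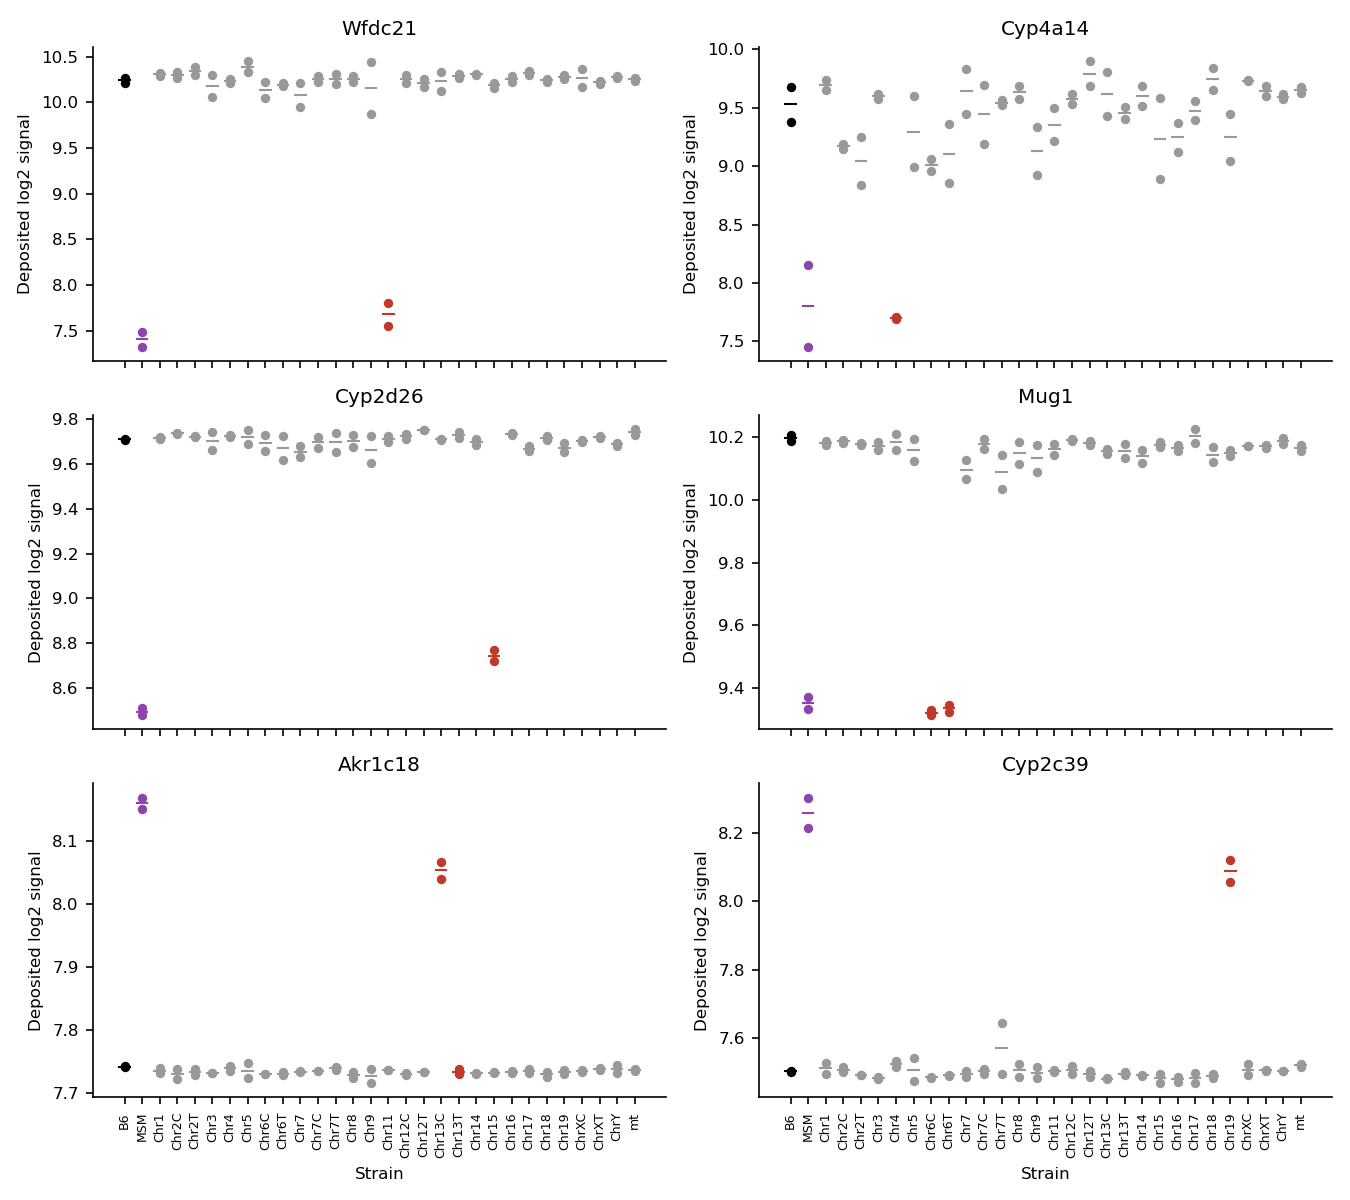
Deposited log2 signal (vertical axes) of 6 genes in the liver of each male, by strain (horizontal axis), with 2 males per strain. MSM and a strain carrying the gene's own chromosome from MSM separate from the other strains, as for Wfdc21 in the Chr11 strain (−2.56 against B6) and Akr1c18 in the Chr13C strain (0.31). For Akr1c18 the Chr13T strain did not separate (−0.0084).

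The comparison of each consomic strain with B6 asked which differences belong to a single chromosome. Many of the MSM differences named above were found again in the strain that carries the gene's own chromosome from MSM. Wfdc21 was lower in the Chr11 strain by −2.56 ± 0.11 (adjusted p = 3.7e-17), which is 90.3% of the MSM difference. Cyp4a14 fell by 1.83 ± 0.22 in the Chr4 strain (106%), Mug1 by 0.88 ± 0.029 in the Chr6C strain (104%) and 0.86 ± 0.029 in the Chr6T strain (102%), and Ugt3a2 by 0.98 ± 0.039 in the Chr15 strain (97.8%). Cyp2d26 fell by 0.97 ± 0.033 in the Chr15 strain (79.4%), Hsd3b3 by 0.67 ± 0.039 in the Chr3 strain (108%) and Ces2a by 0.44 ± 0.018 in the Chr8 strain (82%). Cyp2c39 rose by 0.58 ± 0.028 in the Chr19 strain (77.5%), and Col5a2 by 0.40 ± 0.033 in the Chr1 strain (182%). Hsd3b5 stood at −2.28 ± 0.49 in the Chr3 strain (141%, adjusted p = 0.0146), and the call was lost with either B6 male or either Chr3 male left out (adjusted p from 0.0858 to 0.192).

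Where a chromosome was split between strains, several of these differences passed in 1 part strain and not in the other. Akr1c18 rose by 0.31 ± 0.0071 in the Chr13C strain (adjusted p = 5.52e-25) and stood at −0.0084 ± 0.0071 in the Chr13T strain. Nlrp12 fell by 0.48 ± 0.061 in the Chr7C strain and stood at −0.13 ± 0.061 in the Chr7T strain (adjusted p = 0.563). Acot4 rose by 0.034 ± 0.0038 in the Chr12T strain and stood at 0.000028 ± 0.0038 in the Chr12C strain. The differences between the parts were not tested themselves. Cav1 reached only 38% of its MSM difference in the Chr6C strain (0.13 ± 0.031, adjusted p = 0.0453), and its adjusted p was 0.601 without B6 male 1, 0.213 without B6 male 2 and 0.581 without the second Chr6C male.

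Some MSM differences did not pass in the strain with the gene's own chromosome. Noct stood at 0.012 ± 0.056 in the Chr3 strain, 4.52% of the MSM difference, Scd1 at −0.0093 ± 0.019 in the Chr19 strain (3.57%), Rtp4 at 0.0095 ± 0.0056 in the Chr16 strain (−35.8%) and Hamp at −0.021 ± 0.076 in the Chr7 strain (8.05%). For the metallothionein Mt2 the Chr8 strain stood at 0.91 ± 0.34, 83.5% of the MSM difference, without passing (adjusted p = 0.343). A strain carrying chromosome 10 of MSM, on which Vnn1 and Rdh16f2 lie, was not analysed here.

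Further genes were named in the consomic strains, some of them already given for MSM. Tmem14c (−0.24 ± 0.0090) and Akr1c12 (−0.18 ± 0.0092) fell in the Chr13C strain, Pttg1, the securin of the cell cycle, by 0.13 ± 0.0058 in the Chr11 strain, Gstm2 by 0.14 ± 0.015 in the Chr3 strain, and Ces1g by 0.26 ± 0.018 in the Chr8 strain. Mup3 (−0.37 ± 0.041) and the complement gene C8a (−0.087 ± 0.0083) fell in the Chr4 strain, the carbonyl reductase Cbr1 (−0.057 ± 0.0088) in the Chr16 strain, Fam25c (−0.11 ± 0.017) in the Chr14 strain, and Dsg2 (−0.090 ± 0.010), a desmosomal cadherin, in the Chr18 strain. Cyp46a1, the cholesterol 24-hydroxylase, rose by 0.066 ± 0.0032 in the Chr12T strain, and Dhtkd1 by 0.052 ± 0.0074 in the Chr2C strain. The cystatin Cst3 (−0.014 ± 0.0020) fell in the Chr2T strain and Man2a1 (−0.016 ± 0.0014) in the Chr17 strain. Abhd2 rose in the Chr7 (0.11 ± 0.013), Chr7C (0.094 ± 0.013) and Chr7T strains (0.095 ± 0.013). In the Chr9 strain Paqr9 fell by 0.066 ± 0.0099, and in the Chr5 strain Abhd1 rose by 0.045 ± 0.0016. Alas2, on chromosome X, stood at −0.099 ± 0.016 in the ChrXT strain (adjusted p = 0.00567), and its adjusted p was 0.223 without B6 male 1, 0.147 without B6 male 2 and 0.146 without the second ChrXT male. The naming rule took 186 differences in strains, not all of them printed here, of which 62 passed with each of the 4 males left out and 41 in none of those fits.

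Over the 28 strains, limma made 862 calls on the substituted chromosome and 412 elsewhere, so that 67.7% of calls fell on 4.76% of the genes, summed over strains. For the C and T strains the whole chromosome was counted as substituted, since the labels give no boundary. In 27 of the 28 strains calls were more frequent on the substituted chromosome in Fisher's exact test (two-sided, adjusted p from 8.38e-75 to 0.00261), in which genes are not independent replicates. The Chr7 strain had the most, 81 of 937 genes, followed by the Chr11 strain with 75 of 1019, the Chr5 strain with 70 of 780 and the Chr4 strain with 67 of 758, and the Chr3 strain had the highest share of a nuclear chromosome, 65 of 572 genes (11.4%). On chromosome X, 7 genes were called in the ChrXC strain and 3 in the ChrXT strain (Alas2, Eif2s3x and Trmt2b). Leaving out B6 male 1 left 385 calls on the substituted chromosomes and 30 elsewhere, and leaving out B6 male 2 left 413 and 57. With any other male left out the calls on the substituted chromosomes ranged from 794 to 1084. Counts of single strains moved as well, for the Chr7 strain to 29 and 39 without B6 male 1 and B6 male 2, and to 126 and 32 without its first and its second male. All 120 arrays with the male as a random block put 36.7% of calls on the substituted chromosome, and quantile normalization 16.8%.

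On the substituted chromosomes more genes were lower than higher: 509 of 862 calls, or 59.05% (95% exact interval 55.7 to 62.4). Wfdc21, Cyp4a14, Mug1 and Ugt3a2 are among them. In the calls elsewhere 35.9% were lower, and in MSM 41.5%. With the other strains as reference in place of B6, 62.2% were lower (1029 of 1654). Quantile normalization turned the direction, with 39.7% lower.

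**Figure D2:**
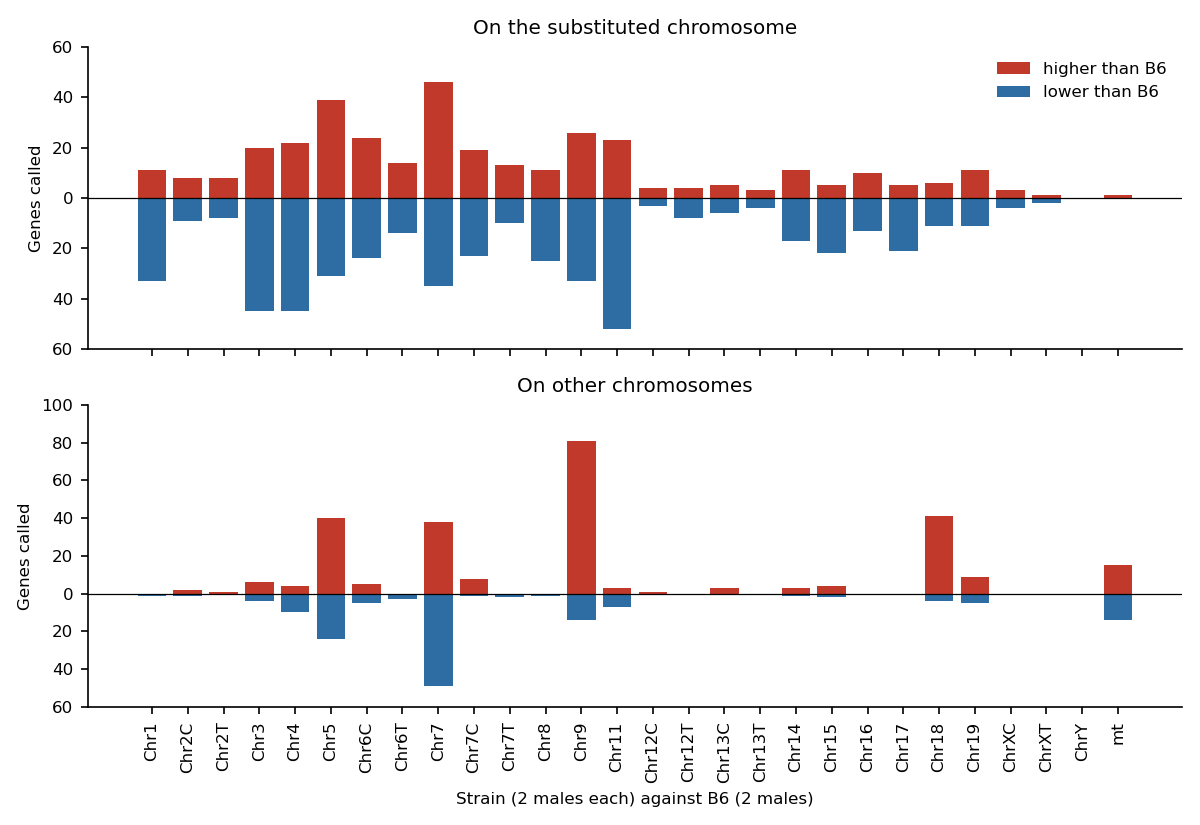
Number of genes called higher (upward) and lower (downward) against B6 on the substituted chromosome and elsewhere, for each of the 28 strains, in 2 panels with strains on the horizontal axis. The Chr7 strain has 81 calls on its chromosome, and the Chr9 (95), Chr7 (87), Chr5 (64) and Chr18 (45) strains have the most calls elsewhere.

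Genes called in a strain mostly changed as they did in MSM. The same probes read MSM alleles in MSM and in a consomic strain. Weaker binding of MSM alleles could therefore also give lower calls on the substituted chromosome that match MSM. This was not tested for these calls, nor for the shares of the MSM difference given below. Of the 862 calls on substituted chromosomes, 732 (84.9%) were also called in MSM in the same direction, 290 of them higher and 442 lower, against 55.2 and 53.3 for independent lists of these sizes, and 1 was called in the opposite direction, Cdc37l1 in the Chr19 strain, a gene chosen after its values were seen. Conversely, of 3923 pairs of an MSM-called gene and a strain carrying its chromosome, 18.7% were called in the strain in the MSM direction, and this share was 3.35% under quantile normalization. Across these pairs the differences correlated with r = 0.795 and a covariance of 15.6, in units of squared residual SD, where genes are not independent replicates. Simulations in which only the B6 males were shared gave r = 0.476 on average (0.237 to 0.690 over 100 draws) and a covariance of 0.469, so part of the excess may come from the shared controls. The B6 group has 2 males and cannot be split. With the other strains, B6 not among them, as control of the consomic strain and B6 still as control of MSM, the correlation was 0.759. The covariance was then 13.97, against 0.0017 for the correlation and 0.00085 for the covariance in simulations of that setting.

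**Figure D3:**
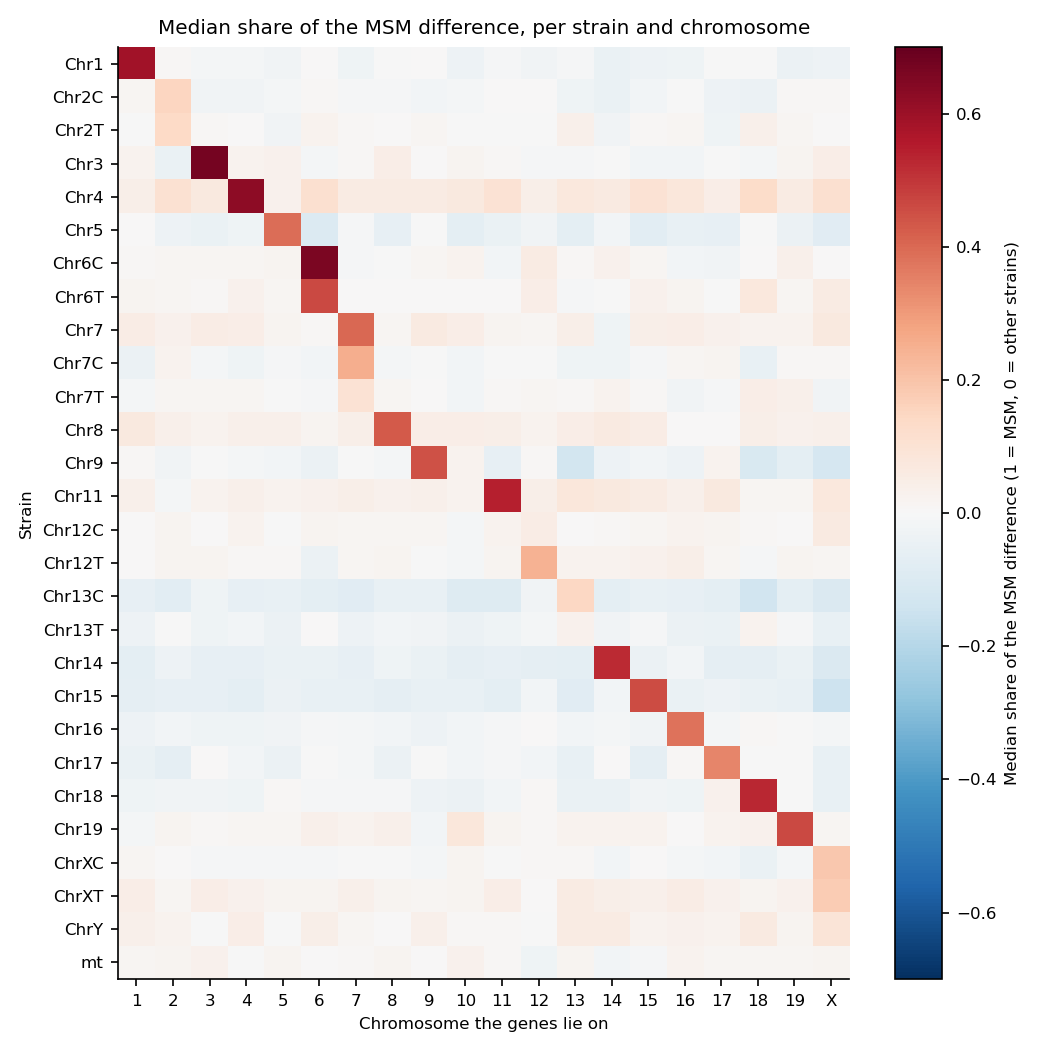
Median share of the MSM difference (colour) over MSM-called genes, for each strain (vertical axis) and each chromosome on which the genes lie (horizontal axis), with the other strains as 0 and MSM as 1. The highest value lies on the substituted chromosome in 25 of 26 strains.

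The share of the MSM difference that a strain carried was concentrated on its own chromosome. In 25 of the 26 strains with a substituted autosome or X chromosome, and in 50 of their 52 males, the median share over MSM-called genes was highest on the substituted chromosome. The strains with a whole single-strain chromosome reached medians from 0.343 on chromosome 17 to 0.669 on chromosome 3. The male exceptions were the first Chr12C male (0.0175) and the first Chr13T male (0.0079). The strain exception was the Chr12C strain, with 0.049 on chromosome 12 and 0.062 on chromosome X. For strains that carry a part of a chromosome the median still runs over the whole chromosome, so it can be low where the part itself has high shares.

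With the tested genes of a chromosome in gene order and in 10 bins of equal size, the part strains carried different stretches of their chromosomes, some of them overlapping. On chromosome 7 the Chr7C strain carried median shares of 0.255 to 0.585 in the first 8 bins and 0.0038 and −0.0068 in the last bins, and the Chr7T strain carried −0.033 to 0.054 in the first 5 bins and 0.299 to 0.598 in the last 5, so that bins 6 to 8 had high shares in both. On chromosome 12 the Chr12C strain carried 0.799, 0.631 and 0.816 in bins 1, 3 and 4, and −0.176 to 0.0149 in the others. The Chr12T strain carried −0.0845 to 0.341 in the first 4 bins and 0.146 to 0.726 in the rest. On chromosome 13 the Chr13C strain carried 0.227 to 0.703 in the first 4 bins and the Chr13T strain 0.677 and 0.420 in the last bins. On chromosome 6 the Chr6C strain carried 0.256 to 1.02 over all 10 bins. The Chr6T strain carried 0.772 and 0.937 in bins 3 and 4, 0.85 and 0.923 in bins 8 and 9, and 0.036 to 0.403 in the others. High shares therefore overlapped in bins 3 and 4, where the Chr6C strain had 0.811 and 0.729. They did so too in bins 8 and 9, where it had 0.889 and 1.02. Mug1 was lower in both strains. On chromosome X the ChrXC strain carried 0.310 to 0.749 in the first 5 bins and the ChrXT strain, with Alas2, 0.207 to 0.685 in the last 5. Some bins held as few as 2 MSM-called genes.

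**Figure D4:**
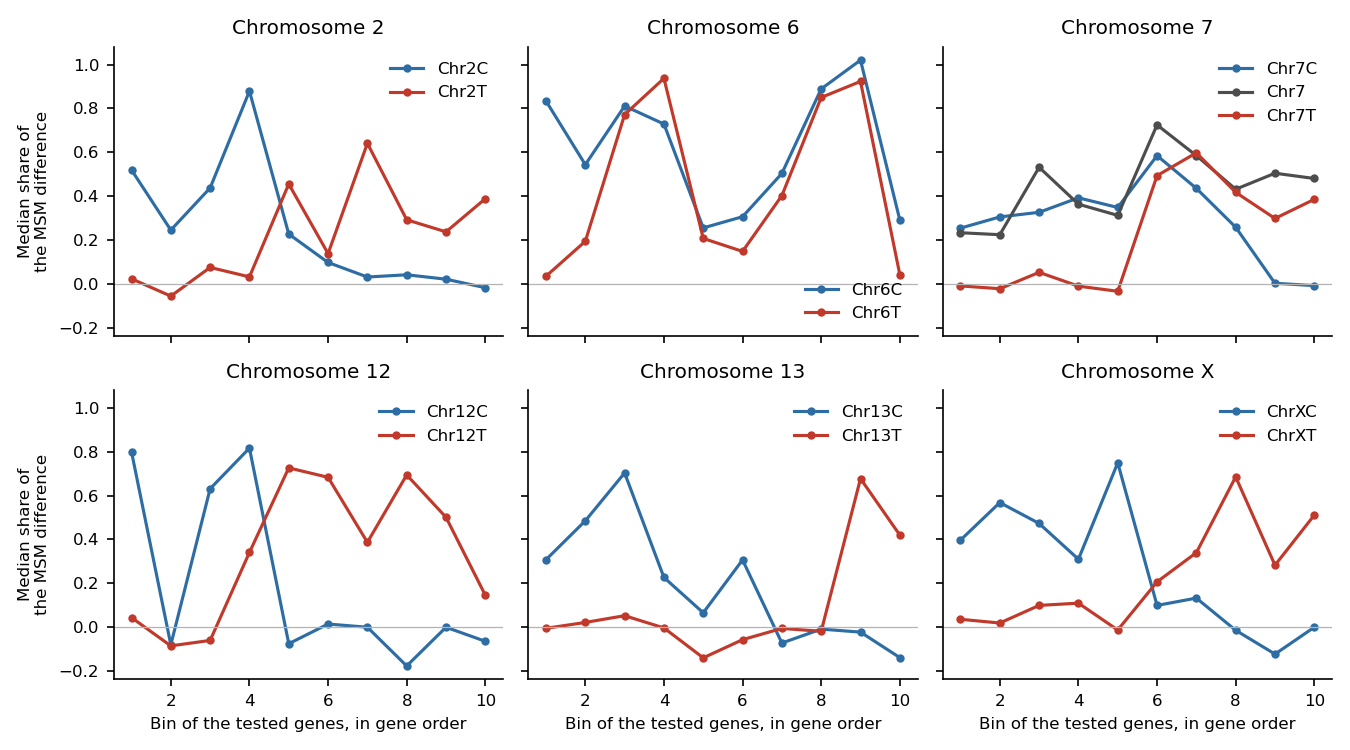
Median share of the MSM difference (vertical axes) in each of 10 bins of the tested genes in gene order (horizontal axis), for the strains that share chromosomes 2, 6, 7, 12, 13 and X. The C and T strains reach high shares in different stretches. These overlap on chromosome 7, as at 0.585 and 0.494 in bin 6. On chromosome 6 the Chr6C strain carries shares in all bins (0.256 to 1.02), and the overlap includes bins 3 (0.772 and 0.811) and 9 (0.923 and 1.02).

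Chromosome 7 was present whole, as its C part and as its T part, which allowed the whole to be compared with the sum of its parts. Of the 81 genes called on chromosome 7 in the Chr7 strain, 23 were also called in the Chr7C strain alone, 11 in the Chr7T strain alone, 9 in both and 38 in neither. Nlrp12 belongs to the first of these groups and Abhd2 to those called in both. The 10 genes called in both part strains all changed in the same direction in each. limma called 5 genes on chromosome 7 in which the whole differed from the sum of the parts, Fam168a, Hnrnpl, Cib1, Clns1a and Tmc5, and none elsewhere (0, with 473 at an unadjusted p below 0.05). These genes were chosen after their values were seen, and all 5 were called in both parts, so that the sum holds each of them from both. For Fam168a the whole strain stood at −0.0054 and the parts at −0.0043 and −0.0052, and the whole exceeded their sum by 0.0040 ± 0.00049 (adjusted p = 3.99e-05). With all arrays and the male as a block, 17 genes were called on chromosome 7 and 17 elsewhere, and under quantile normalization 1 and 1.

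Calls on chromosomes other than the substituted one numbered 412, and 203 of them were also called when the other strains served as the reference. Of these 72 were in the Chr9 strain, which had 4 calls elsewhere without its first male, 40 in the Chr7 strain and 31 in the Chr5 strain, and 131 were left without the Chr9 strain. Vnn1, the pantetheinase on chromosome 10, fell in the Chr6C strain by 0.28 ± 0.049 (adjusted p = 0.00209) and in the Chr6T strain by 0.23 ± 0.049 (adjusted p = 0.0291). Its call was lost in the Chr6C strain without B6 male 1 (adjusted p = 0.194) or the first Chr6C male (0.242), and in the Chr6T strain without any of the 4 males (adjusted p from 0.063 to 0.993). The bile salt transporter Abcc3, on chromosome 11, fell in the same strains by 0.0025 ± 0.00052 and 0.0030 ± 0.00052. Those calls too were lost without B6 male 1 (adjusted p = 0.733 and 0.267), and in the Chr6C strain also without its first male (0.527). Bcl7c, on chromosome 7, fell by 0.030 ± 0.0038 in the Chr14 strain (adjusted p = 4.04e-05), and Irf5, an interferon regulatory factor on chromosome 6, rose by 0.00087 ± 0.00011 in the Chr2C strain. Both calls held with each of the 4 males left out. Me1, which encodes malic enzyme and lies on chromosome 9, also stood lower in the Chr2C strain (−0.029 ± 0.0055, adjusted p = 0.00825), and its adjusted p was 0.714 without B6 male 1 and 0.276 without the second Chr2C male. Nnt, the mitochondrial transhydrogenase on chromosome 13 that is truncated in C57BL/6J, fell by 0.034 ± 0.0052 in the Chr1 strain (adjusted p = 0.000357, and 0.101 without the second Chr1 male) and rose by 0.031 ± 0.0052 in the Chr13T strain, a call that was lost with any of the 4 males left out (adjusted p from 0.100 to 0.178).

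The Chr9 strain had the most calls elsewhere, 81 higher and 14 lower. The cornified envelope gene Sprr1a rose by 0.034 ± 0.0088 (adjusted p = 0.0482), and the steroid reductases Akr1c14 (−0.011 ± 0.0025) and Tm7sf2 (−0.0086 ± 0.0020), the latter of cholesterol synthesis, fell. On chromosome 9 itself the membrane-binding Anxa2 rose by 0.11 ± 0.028 (adjusted p = 0.0416). All of these were lost without the first Chr9 male (adjusted p = 0.990, 0.807, 0.935 and 0.955) and without either B6 male (adjusted p from 0.133 to 0.307). The first Chr9 male stood apart from the other 59 males: in 98 genes it lay above them by more than their whole range and in 1 below, where the median male had 0 such genes. Anxa2 read 8.37 in it and at most 8.22 in the others. It was the highest of the 60 males in 16 of 25 measured cell cycle genes, 11 of 15 stellate and fibroblast markers and 9 of 18 Kupffer cell markers, and the lowest in 13 of 40 xenobiotic metabolism genes and 13 of 41 respiratory chain genes. Without this male the Chr9 strain had 4 calls elsewhere, without its second male 2115, without B6 male 1 it had 2 and without B6 male 2 it had 5. Quantile normalization left 20, and the panel reference gave 591.

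The Chr7, Chr5 and Chr18 strains followed with 87, 64 and 45 calls elsewhere. Against the other strains 40, 31 and 5 of these held, and Vapb and Hnrnpl in the Chr18 strain, given below, did not. In the Chr7 strain the fasting hormone Fgf21, on chromosome 7, rose by 0.10 ± 0.026 and the pyruvate dehydrogenase kinase Pdk4, on chromosome 6, by 0.098 ± 0.025. Both were lost without the second Chr7 male (adjusted p = 0.767 and 0.546) and without either B6 male (adjusted p from 0.199 to 0.228). The second Chr7 male had the highest Fgf21 of all 60 males, 7.68 against at most 7.56, and the highest value in 9 of 21 measured cytosolic ribosome genes. The calls elsewhere came to 670 without the first Chr7 male, 15 without the second, and 9 and 6 without B6 male 1 and B6 male 2. In the Chr5 strain Csad, an enzyme of taurine synthesis, fell by 0.14 ± 0.028 and the nuclease Dnase2a by 0.11 ± 0.026, and both were lost without the second Chr5 male (adjusted p = 0.277 and 0.547) and without B6 male 1 (0.155 and 0.266), Dnase2a also without B6 male 2 (0.143). This second Chr5 male was the highest of the 60 in 14 of 28 acute phase genes. The calls elsewhere in the Chr5 strain came to 175 without its first male, 8 without its second, and 4 and 11 without the B6 males. In the Chr18 strain they came to 1 and 18 without its own males and 4 and 6 without the B6 males, and Vapb (0.012 ± 0.0027) and Hnrnpl (0.0040 ± 0.00064) were among the 41 called higher as deposited, the first lost with any of the 4 males left out (adjusted p from 0.153 to 0.411) and the second without the first Chr18 male (0.157).

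Several genes were called in more than 1 strain away from the substituted chromosome. Of 325 genes called elsewhere, 54 were called in at least 2 strains and 18 in at least 3. In 1000 random draws of as many genes, 5.88 on average and 15 at most reached at least 2 strains. At most 2 reached at least 3. The draws took the strains as independent, but the contrasts share the B6 males and the residual SD of each gene. An excess over the draws is therefore no evidence of an effect common to the strains. Nfic, a transcription factor, was higher in 7 strains, and the plasma copper protein Cp and Mvb12a in 5 each. In these genes the B6 males ranked first and second from the bottom of all 60 males. Against the other strains in place of B6, Nfic was called in 0 strains, Cp in 1 and Mvb12a in 0. Without B6 male 1 there were 3 such genes in at least 2 strains, without B6 male 2 there were 5, and without the second Chr9 male 206. All arrays with a male block gave 492, and quantile normalization 476.

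The strain carrying MSM mitochondria had 1 gene called on the mitochondrial genome, ND5 of respiratory complex I, which rose by 0.00083 ± 0.00012 (adjusted p = 0.00086, and 0.173 without B6 male 1). It had 29 calls elsewhere, among them Oit3, an endothelial marker, which fell by 0.00043 ± 0.000055 (adjusted p = 0.00012). Oit3 turned to 0.000044 under quantile normalization. Without B6 male 1 the calls elsewhere came to 1, without B6 male 2 to 5 and without either male of the strain to 2. In the ChrY strain limma called 0 genes, with 1 gene on chromosome Y and 531 elsewhere at an unadjusted p below 0.05. Its Sry stood at 0.000054 ± 0.000022 (adjusted p = 1).

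With B6 as the reference, several gene lists stood on the same side in many strains. The bile acid list was lower than other genes in camera in all 28 strains, and 19 of these passed with a preset correlation. Against the other strains it passed as higher in 1 and lower in 2. With an estimated correlation none (0) of the 870 tests of 30 lists in 29 contrasts against B6 passed as deposited (64 at an unadjusted p below 0.05, lowest adjusted p = 0.105), and 5 passed against the other strains: PPARA targets lower in the Chr2C strain (adjusted p = 0.0338), complement and coagulation genes lower in the Chr4 strain (0.0181), ribosome genes higher in the Chr7 strain (0.0105), cholesterol synthesis higher in the Chr7T strain (0.00126) and endothelial markers lower in the strain with MSM mitochondria (0.00366). The Chr7T result may rest on the first Chr7T male, which carried female-type transcripts, as described below. It had the highest reading of all males in 16 of 20 cholesterol synthesis genes, where the next male had 2. The list was not tested without this male, so no effect of the strain can be read from it. Likewise, the Chr7 result may rest on the second Chr7 male. It was the highest of all males in 9 of 21 measured ribosome genes, where the next male had 4. The ribosome list was not tested without this male either. The counts that follow use the preset correlation. Fatty acid synthesis passed as lower in 15 strains (against the other strains 3 higher and 3 lower), PPARA targets as lower in 13 (6 and 6), cholesterol synthesis as lower in 14 and higher in 2 (9 lower and 7 higher), and circadian genes as lower in 9 and higher in 1 (2 lower and 1 higher). MHC genes passed as higher in 13 strains (4 and 4), acute phase genes as higher in 10 (5 higher and 2 lower) and Kupffer cell markers as higher in 8 (5 higher and 2 lower). Under quantile normalization MHC genes passed as higher in 4 strains and lower in 1, acute phase genes as higher in 4 and lower in 4. Over all 870 tests, 178 passed with the preset correlation, and fry passed 6. Quantile normalization with an estimated correlation passed 56.

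**Figure D5:**
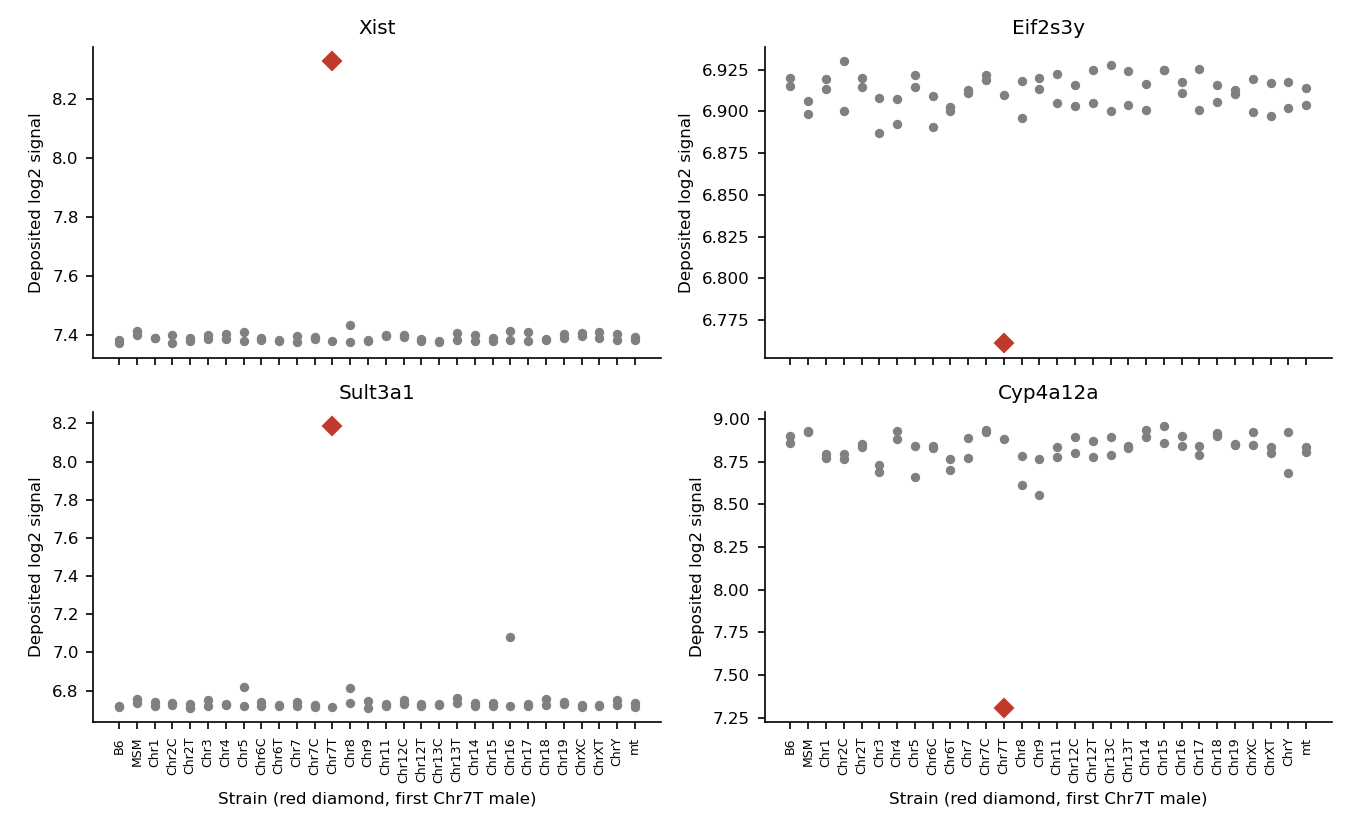
Deposited log2 signal (vertical axes) of Xist, Eif2s3y, Sult3a1 and Cyp4a12a in each of the 60 males, by strain (horizontal axis), with the first Chr7T male as a red diamond. Xist reads 8.33 in this male and 7.37 to 7.44 in the other 59, and Cyp4a12a reads 7.31 against at least 8.56.

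The Chr7T strain had 23 calls on chromosome 7, with Nlrp6 (−0.027 ± 0.0025) and Abhd2 among them, and 2 calls elsewhere, Enpp3 (−0.011 ± 0.0023) and Ccnt2 (−0.00016 ± 0.000035). Its first male differed from all others in sex-dependent transcripts. Xist, the transcript of the inactive X chromosome, read 8.33 in it and 7.37 to 7.44 in the other 59 males, and Eif2s3y, on chromosome Y, read 6.76 against 6.89 to 6.93. The female-predominant Sult3a1 (8.19, at most 7.08 in the others), Cyp2b9 (7.95, at most 7.54), Cyp2b13 (7.69, at most 7.33) and Sult2a2 (7.58, at most 6.93) were highest in this male, and the male-predominant Cyp4a12a (7.31, at least 8.56 in the others) was lowest. It was the highest of the 60 in 11 of 14 female-biased genes, 16 of 20 cholesterol synthesis genes and 13 of 34 interferon genes, and the lowest in 7 of 15 male-biased genes. These genes were chosen after their values were seen, except for the lists. Without the first Chr7T male the strain had 11 calls on chromosome 7 and 2 elsewhere, and without its second male 38 and 129. Without B6 male 1 it had 9 and 0, and without B6 male 2 it had 14 and 0. Enpp3 was lost without either B6 male (adjusted p = 0.293 and 0.212) or the first Chr7T male (0.790), and Ccnt2 likewise (0.490, 0.248 and 0.471).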

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

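The tests of next brightest probe sets, of the other strains as reference, of female-biased genes, of Xist, of the first bins of chromosome 7, of array factors and of the distance of the first Chr9 male were chosen only after the results they concern were seen. The groups hold 2 males each, which is too few to test a male against its group, so single males were compared with the other 59 males and, in the Chr9 strain, with the second male.

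In 5 genes on chromosome 7 the Chr7 strain differed from the sum of the Chr7C and Chr7T strains by a test of that difference, as described above. All 5 were called in both part strains, so the sum holds each from both. The test cannot tell such an overlap of the parts from a whole that departs from them. For Hnrnpl it cannot set apart low readings of the B6 males either. Hnrnpl was also called higher in the Chr5, Chr9, Chr18 and mt strains, by a mean of 0.0032. Its difference in the Chr7T strain was 0.0030. In this gene the B6 males ranked 1 and 2 from the lowest of all males. With the other strains as reference it was called elsewhere in 0 strains. Among the 10092 probe sets without a single gene symbol, which enter no comparison above, 3122 passed the filter, and limma called 588 of them in MSM, 346 higher and 242 lower, with 1056 at an unadjusted p below 0.05. Clps, a pancreatic colipase gene below the filter, read 7.38 in the second ChrXT male and at most 7.36 in the other 59 males. Gkn1 (7.58 against at most 7.55), Gkn2 (7.73, at most 7.70), Pla2g1b and Pgc were also highest in this male. Cela1 (8.275, with 8.285 in another male) and Ctrb1 were not.

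The calls on the substituted chromosomes were lower more often than higher (59.05%). The next brightest probe set of the genes called lower shared the sign in 86.11% of 288 genes (95% exact interval 81.6 to 89.9), against 78.6% for those called higher, but calls elsewhere, without MSM alleles, showed a similar gap (90.72% and 80.25%). If weaker binding of MSM alleles were the whole cause and the excess genes shared it by chance, 78.2% would be expected from the lower calls elsewhere (73.0 to 81.7 over their interval), which reaches the interval observed, so this cause cannot be told apart from lower expression of MSM alleles, which was not tested. High readings of both B6 males as the cause would have brought the share near 50% against the other strains, where it was 62.21% (59.8 to 64.6). Quantile normalization gave 39.7% lower, but it moved most genes of some strains the same way (87% higher in the Chr17 strain, 85.3% in the Chr6C strain), so it decides nothing about the direction.

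The first Chr7T male carried female-type transcripts, with Xist above and Eif2s3y, Kdm5d and Uty below all 59 other males. Of 7 measured Y chromosome genes 3 were lowest in this male. Eif2s3y, Kdm5d and Uty lay below the filter, and the last 2 differed little: Kdm5d read 7.1311 against at least 7.1312, and Uty 7.1492 against at least 7.1494. The highest reading of the 60 males lay in this male for 11 of 14 measured female-biased genes, so its liver RNA may have come from a female or been mixed with female RNA, while Cux2 ranked 44 of 60 and 7 of 15 male-biased genes were lowest in it. A wrong label from another strain of the panel is argued against, since this male carried 0.1757 of the MSM difference on chromosome 7 (0.1397 in the second male), and in its first 5 bins 0.0395, where the Chr7 and Chr7C males had at least 0.259. An altered hormone status of a male as the whole cause is argued against, since it would leave Xist and the Y-linked genes in the range of the other males, and Xist read 8.33 against at most 7.44.

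Most calls elsewhere in the Chr9 strain rest on its first male. With 5 array factors removed, 262 genes were called elsewhere, against 95 as deposited. The removal also moved the counts of other strains, in the Chr18 strain from 45 to 75 and in the Chr7 strain from 87 to 34. The higher count alone therefore decides nothing. Of the 95 calls 76 were kept, which argues against differences between arrays of a male as the cause of those 76. The factors hold only such differences, so a technical effect common to both arrays of the first male was not tested and stays open. In 95.79% of the 95 called genes (95% exact interval 89.6 to 98.8) the first male lay further from the other strains than the second, so the calls may reflect the state of 1 liver. For 49 genes outside chromosome 9 in which the first male stood beyond all males of other strains by more than their range, the second male lay on the same side in 38.776% (25.2 to 53.8), which argues against a substitution acting in both males for those genes. Over all 95 calls, which were selected on the mean of both males, they lay on the same side in 86, with the second at a median of 23.4% of the distance of the first, so a smaller effect of chromosome 9 in both males stays open, as does the state of the liver.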

How the results depend on the processing

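Of 585 counts recomputed under an alternative, 221 stayed within 1.5 times the count as reported. Of the 281 differences taken by the naming rule, the same direction and side of the threshold were kept by 275 with trend and robust moderation, 267 with all arrays and the male as a block, 249 without a filter, 239 of 266 with the mean over probe sets, 236 of 239 with the stricter filter and 179 under quantile normalization. Leaving out 1 male kept the call in 664 of 1124 fits, and no direction turned in the other 460. The removal of array factors, the estimated correlation after quantile normalization and the fits without the first Chr9 male or the first Chr7T male were chosen after seeing the data. Without the first Chr7T male 1752 genes were called higher and 1253 lower in MSM, and 59.7% of the calls on substituted chromosomes were lower. No paired analysis was possible because the animal numbers are not shared between strains. The alternative pseudocount was not run, since the deposited values are already logarithms. No test for a single male off its group was made within groups of 2. Except where stated, the cause of a change was not tested.

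Each male of the compared strains was left out in turn, and the male left alone was assumed to vary like the other groups. The MSM counts of 1731 higher and 1226 lower then ranged from 919 to 1046 and from 705 to 878. Calls on the substituted chromosome are given next, with the lowest and highest count in parentheses. Chr1 had 44 (15 to 25), Chr2C 17 (9 to 11), Chr2T 16 (4 to 10), Chr3 65 (33 to 43), Chr4 67 (34 to 38), Chr5 70 (24 to 60) and Chr6C 48 (23 to 27). Chr6T had 28 (9 to 20), Chr7 81 (29 to 126), Chr7C 42 (20 to 27), Chr7T 23 (9 to 38), Chr8 36 (12 to 18), Chr9 59 (24 to 172) and Chr11 75 (37 to 70). Chr12C had 7 (4 to 5), Chr12T 12 (8 to 10), Chr13C 11 (5 to 7), Chr13T 7 (1 to 2), Chr14 28 (10 to 18), Chr15 27 (15 to 18) and Chr16 23 (9 to 12). Chr17 had 26 (11 to 20), Chr18 17 (9), Chr19 22 (5 to 11), ChrXC 7 (2 to 4), ChrXT 3 (1 to 2), ChrY 0 (0) and mt 1 (0 to 1). Those elsewhere follow in the same form. Chr1 had 1 (0 to 2), Chr2C 3 (1 to 4), Chr2T 1 (0 to 1), Chr3 10 (1 to 6), Chr4 14 (0 to 2), Chr5 64 (4 to 175) and Chr6C 10 (0 to 24). Chr6T had 3 (0 to 11), Chr7 87 (6 to 670), Chr7C 9 (0 to 3), Chr7T 2 (0 to 129), Chr8 1 (0 to 1), Chr9 95 (2 to 2115) and Chr11 10 (1 to 102). Chr12C had 1 (0), Chr12T 0 (0 to 3), Chr13C 3 (0 to 2), Chr13T 0 (0), Chr14 4 (2 to 5), Chr15 6 (0 to 4) and Chr16 0 (0 to 1). Chr17 had 0 (0 to 6), Chr18 45 (1 to 18), Chr19 14 (0 to 2), ChrXC 0 (0 to 5), ChrXT 0 (0 to 6), ChrY 0 (0 to 1) and mt 29 (1 to 5). Where limma called 0 genes elsewhere, 410 (Chr13T) to 575 (Chr16) had an unadjusted p below 0.05.

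Quantile normalization called 9785 genes higher and 344 lower in MSM, and 2550 genes were called in MSM both as deposited and after it. It turned the direction of the calls on the substituted chromosomes to 39.7% lower, put 16.8% of calls there and left 3.35% of MSM-called pairs called in the MSM direction. It gave 476 genes called elsewhere in several strains, and 1 gene on chromosome 7 and 1 elsewhere in the comparison with the part strains. Single differences turned sign for Clec4g (0.00040), Pcna (0.00043), Pgm1 (9.8e-05) and Rps6 (0.00047) in MSM, Oit3 in the mt strain (4.4e-05), Rbbp4 in the Chr11 strain (−0.0020), Rpl41 in the Chr13C strain (−1.5e-05) and Trappc12 in the Chr8 strain (9.3e-05), all without passing. Calls on the substituted chromosome moved by more than 1.5 times as follows. Chr1 had 12, Chr2C 8, Chr2T 4, Chr3 31, Chr4 43, Chr5 23, Chr7C 19 and Chr7T 8. Chr8 had 11, Chr9 15, Chr11 29, Chr12C 4, Chr13C 7, Chr13T 1, Chr14 7 and Chr15 16. Chr16 had 14, Chr17 86, Chr18 7, Chr19 13, ChrXC 3, ChrXT 1 and mt 0. Elsewhere the counts became these. Chr1 had 6, Chr3 39, Chr4 65, Chr5 13, Chr6C 746, Chr6T 155, Chr7 234, Chr8 29 and Chr9 20. Chr11 had 30, Chr12C 0, Chr14 24, Chr16 7, Chr17 1059, Chr18 7, ChrXC 1 and mt 2.

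With all arrays and the male as a random block, 36.7% of calls lay on the substituted chromosome, 25.3% of MSM-called pairs were called in the MSM direction, and 492 genes were called elsewhere in several strains. The comparison with the part strains gave 17 genes on chromosome 7 and 17 elsewhere. On the substituted chromosome these counts moved. Chr1 had 86, Chr2C 33, Chr2T 28, Chr6T 43, Chr7 143, Chr7C 70, Chr7T 60, Chr8 60, Chr9 116 and Chr11 119. Chr12T had 25, Chr13C 20, Chr13T 12, Chr14 45, Chr15 42, Chr16 35, Chr17 41, Chr19 46, ChrXC 14 and ChrXT 6. So did these elsewhere. Chr1 had 29, Chr2C 55, Chr2T 7, Chr3 110, Chr4 33, Chr5 276, Chr6C 60, Chr6T 24 and Chr7 482. Chr7C had 30, Chr7T 105, Chr8 40, Chr9 774, Chr11 144, Chr12C 7, Chr12T 10, Chr13C 18 and Chr13T 4. Chr14 had 47, Chr15 17, Chr16 17, Chr17 15, Chr18 73, Chr19 40 and ChrXC 24.

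With the other strains as reference, 59.4% of calls lay on the substituted chromosome. More strains in the reference give it a smaller error by construction. The counts there that moved were these. Chr1 had 85, Chr2C 35, Chr2T 36, Chr3 111, Chr4 103, Chr5 120, Chr6C 80, Chr6T 58 and Chr7 138. Chr7C had 82, Chr7T 63, Chr8 72, Chr9 136, Chr11 146, Chr12C 12, Chr12T 30, Chr13C 20 and Chr13T 14. Chr14 had 61, Chr15 72, Chr16 39, Chr17 59, Chr19 42, ChrXC 12 and ChrXT 6. For calls elsewhere they were the following. Chr2C had 6, Chr2T 5, Chr3 17, Chr4 32, Chr6T 7, Chr7 152, Chr7T 39, Chr8 4, Chr9 591 and Chr11 26. Chr12C had 0, Chr12T 3, Chr13C 7, Chr14 30, Chr15 51, Chr16 2, Chr17 15, Chr18 19, Chr19 7 and ChrXC 1.

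Without a filter, 18193 genes were tested, 75.1% of calls lay on the substituted chromosome, 16.6% of pairs were called in the MSM direction and 34 genes were called elsewhere in several strains. The ChrXT strain had 7 calls on chromosome X. Calls elsewhere changed in these strains. Chr2T had 2, Chr4 8, Chr6C 6, Chr7 57, Chr12C 0, Chr12T 1, Chr18 27, Chr19 8, ChrXT 1 and mt 18. With the mean over probe sets these shares were 71.8% and 22.99%. On the substituted chromosome the counts were as follows. Chr12C had 14, Chr12T 20, Chr13T 13, Chr19 39 and ChrXT 1. Other chromosomes changed too. Chr2T had 2, Chr4 8, Chr7C 4, Chr7T 5, Chr8 2, Chr12T 1, Chr17 2 and Chr19 25. The mean turned Cp in the Chr5 strain (−0.00013), Rps3 in the Chr7 strain (−0.00012) and MSM (−0.00020, adjusted p = 0.00371, and 0.0255 to 0.878 over the other alternatives), and Pdxdc1 in the Chr16 strain (0.014, adjusted p = 1.21e-17, against −0.030 as reported and adjusted p from 1.36e-26 to 1.40e-12 over the other alternatives, all negative).

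With 5 array factors removed, the calls elsewhere moved in many strains. Chr7 had 34, Chr9 262, Chr18 75 and mt 46. Chr1 had 6, Chr3 25, Chr6T 9, Chr7T 11, Chr8 5, Chr11 26, Chr12T 5, Chr13T 1, Chr14 11, Chr15 11, Chr17 17 and Chr19 7. On the substituted chromosome the counts rose by more than 1.5 times in the following. Chr2C had 38, Chr6T 47, Chr7C 64, Chr7T 40, Chr9 108, Chr12T 24 and Chr13C 18. Chr13T had 11, Chr14 46, Chr15 58, Chr18 39, Chr19 34 and ChrXC 11. Of the calls on substituted chromosomes 62.7% were lower, 22.3% of pairs were called in the MSM direction and 89 genes were called elsewhere in several strains. Without the first Chr9 male the Chr7 strain had 226 calls elsewhere, and 64.2% of all calls lay on the substituted chromosome. A minimum change of 1 left 1 MSM gene higher and 5 lower. A fit on MSM and B6 alone called 581 higher and 739 lower with 2 residual degrees of freedom. With an estimated correlation, camera called 0 of the 178 list shifts found with the preset correlation, and 64 of all 870 had an unadjusted p below 0.05. After quantile normalization it called 56.

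Array signals include background, and no probe set here had a detection call. A gene near the floor can therefore move little whatever its transcript does, and the shrunken deviations leave the size of a difference without a meaning across genes.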

Other observations

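The tests of B6 against the panel and of the neighbours of Nnt were chosen only after the results they concern were seen, and the test of the strains carrying a gene's own chromosome before. Other single males also stood out in gene lists, where a male would be the highest in fewer than 1 gene of each list on average. The second Chr5 male was the highest of 60 in 14 of 28 acute phase genes, 6 of 29 complement and coagulation genes and 6 of 12 endothelial markers, and the lowest in 6 of 15 heat shock genes. In the second ChrXC male 10 of 20 MHC and antigen presentation genes were highest, and in the first Chr15 male 7 of 21 circadian genes. Of 21 cytosolic ribosome genes 11 were lowest in the first Chr17 male, and 8 of 22 endoplasmic reticulum stress genes were lowest in the first Chr1 male. Among the genes called elsewhere in the Chr7 strain the first male lay further from the other strains than the second in 21.8% (95% exact interval 13.69 to 31.98), in the Chr5 strain in 31.3% and in the Chr18 strain in 60%.

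Among the genes called elsewhere in most strains against B6, both B6 males lay at the end of the range in some, such as Nfic, Cp and Mvb12a, and not in others, such as Irf5 (ranks 5 and 7 of 60), Crbn (47 and 52) and Eif3e (46 and 54). Of the 54 genes called elsewhere in at least 2 strains, 8 were also called elsewhere in at least 2 strains with the other strains as reference, so most of this recurrence may come from B6 males that lie off the mean of the panel. Against that reference 66 genes recurred in all, where random draws gave 35.9 on average and 54 at most. These draws also took the strains as independent, though their contrasts share the residual SD of each gene, so this excess decides nothing.

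Of the 203 calls elsewhere that held against the other strains (131 without the Chr9 strain), 77 lay in genes called in MSM (57), where independent lists of these sizes would share 50.2 (32.4), but both sets of calls rest on the same B6 males. Of the 77, 20 were opposite in direction to MSM, and 46 went in the MSM direction in genes also called in MSM against the other strains. A substituted chromosome might carry the MSM difference of a gene that lies on another chromosome. In 40 calls in the MSM direction, in genes also called in MSM against the other strains and with a strain that carries the gene's own chromosome, that strain (the highest where there were several) held a median of 29.39% of the MSM difference (28.46% without the Chr9 strain). The strain with the call held 91.67%, a share taken over calls selected for passing in that direction. The own-chromosome share was below 25% in 17 of the 40 and at least 50% in 18, so acting at a distance and acting from the gene's own chromosome cannot be told apart for these calls as a set. Bcl7c, on chromosome 7, stood at 108% in the Chr14 strain and at most 10.9% in the strains carrying its own chromosome.

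Nnt stood at 8.09 in both B6 males and 8.12 in both MSM males, and its difference from B6 was −0.034 in the Chr1 strain and 0.020 in the Chr18 strain (adjusted p = 0.0692). A stretch of MSM chromosome 13 left in these strains would raise Nnt, which excludes it for the Chr1 strain, where Nnt fell. The median share of the MSM difference over the 10 nearest MSM-called genes was at most 0.00256 in either strain, against 0.396 in the Chr13T strain, which argues against a stretch that reaches these neighbours in the Chr18 strain as well. No biological explanation was tested.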
